A study of Brachypodium distachyon with 6 samples.

How the data were processed

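Messenger RNA was measured by RNA sequencing in whole roots of Brachypodium distachyon Bd21, the inbred reference line of this model grass. Per the labels' protocols, each of the 6 libraries came from a pool of 12 seedlings. The seedlings were moved to hydroponic tanks of 4.5 L at 7 days of age and grown for 19 days at 2.5 mM nitrogen. Nitrogen was given as 1.25 mM ammonium sulfate (3 libraries) or 1.25 mM calcium nitrate (3 libraries), so the counter-ion changes together with the nitrogen source. Per the labels' protocols, RNA was purified with poly-T beads and libraries were made with the NEBNext Ultra RNA kit, primed with random hexamers. No sequencing batch, and no statement that the kit marks strand, is given in the labels.

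The authors deposited 1 table of raw read counts per feature and library. Per the submitters' processing notes, HISAT2 and HTSeq were used. Their versions, the genome build, the annotation and the counting options (strand, overlaps, reads with several alignments) are not given in the sources used here. The table holds 29627 features and no duplicated identifier. Of these, 29435 have locus identifiers of the form BRADI and 192 have identifiers with the prefix ENSRNA, which the table does not describe further. Every feature has at least 1 count in at least 1 library. No row names a total or unassigned reads.

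The table pairs identifiers with no gene names. None of the identifiers (0 of 29627) matched the RefSeq gene table used for names, which lists 31335 genes of assembly Brachypodium_distachyon_v3.0, by gene number, locus tag, symbol, synonym or accession. Removing the version suffix and punctuation still gave 0 matches. Gene symbols, product names and coordinates are therefore not reported here. For the same reason the 38 gene lists (nitrogen uptake and assimilation, hormones, ions, cell wall, markers of other tissues and the like), which had been fixed as patterns on product names before the data were examined, were not tested (0 of 38). The digit after the BRADI prefix was read as the chromosome, and the number after it as the order of loci, by the naming convention of this species.

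Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, after its filterByExpr function (minimum count 10, minimum total 15) and TMM scaling. The fit used all 6 libraries with nitrogen source as the only term. P-values were adjusted by the Benjamini-Hochberg method, and a feature was called at an adjusted p under 0.05. The filter removed 5933 features and left 23694, which held over 99.9% of the counts of each library. Log2 fold changes are ammonium over nitrate. Their standard errors (SE) were taken as the fold change divided by the square root of F. CPM values were computed from the counts with TMM-scaled library sizes. A log2 CPM with a prior count of 2 was used for correlations and principal components.

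The rule for named features was fixed before the data were examined: the features with the largest absolute log2 fold change, past the threshold, with a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. Its condition on the product name could not be applied, and the rule then limits the text to 2 identifiers per direction.

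Library totals ran from 22470936 to 29547877 counts. Replicate pairs were compared to find libraries deposited more than once. The chi-square per degree of freedom between libraries of the same treatment was at least 6.79, above the value of 1 that counting noise alone gives, so all 6 were kept as separate samples. The labels do not say that the pools of a treatment came from separate tanks. P-values therefore measure the spread between these pools, which may be partly technical. Intervals on counts cover counting error only, since reads carried no molecular identifiers.

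The replicate numbers 1 to 3 are shared by both treatments. Deviations from the group mean correlated at 0.11 to 0.21 (Pearson's r across features, which are not independent replicates) between libraries of the same number, and at -0.13 to -0.02 between libraries of different numbers. The second principal component also set both libraries numbered 3 apart. Deviations within a group cancel out, so positive values for some pairs force negative ones for others, which are no separate evidence. Any pairing is thus read from the data and not from the labels. A fit with the replicate number as a block was run as an alternative.

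The test was checked on simulated counts with the means and library sizes of this comparison, 200 changed features each time, 8 simulations per kind and 23470 to 23497 features tested. With dispersions on the fitted trend, it recovered 33.8% of features changed by 0.5 on the log2 scale, 88.4% of those changed by 1 and 100% of those changed by 2, and 4.61% of calls were false. With dispersions that vary between features, the shares were 19.7%, 84.5% and 99.2%, and 10.3% of calls were false (23474 to 23486 features tested). Unadjusted p-values of unchanged features fell under 0.05 in 4.92% and 4.80% of cases, respectively. The changed features were drawn from those with a mean of at least 1 CPM, so the recovery of rarer features was not measured. With 200 changed features the adjusted threshold is stricter than in the real comparison, so the shares recovered do not measure the recovery of small changes there. The shares of false calls do not carry over either, since far more features were called there. The false share of the real calls was not measured.

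The alternatives were DESeq2 size factors, library size alone, the DESeq2 1.42.0 Wald test, limma-voom (limma 3.58.1), no filter, a filter of 1 CPM in 3 libraries, the replicate block, a 2-fold minimum, and leaving out each library in turn. Thinning to equal depth and robust dispersions were added after the data had been seen.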

Results

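The root transcriptome of Brachypodium distachyon Bd21 was compared between plants fed ammonium and plants fed nitrate as the exclusive nitrogen source. The series asks how the form of nitrogen affects root gene expression in this grass. There were 3 ammonium and 3 nitrate libraries, each from a pool of 12 seedlings. The ammonium libraries held 29547877, 27746315 and 27525771 counts (replicates 1 to 3) and the nitrate libraries 29115598, 26259405 and 22470936. The number of features with at least 1 count was 27404 ± 87.0 (SD, n = 3) under ammonium and 27402 ± 149 (SD, n = 3) under nitrate, a difference smaller than the spread between replicates (exact permutation test, two-sided p = 0.9). With 3 libraries against 3, the smallest p that this test can give is 0.1.

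Nitrogen source was the main axis of variation between the root libraries. The first principal component held 79.0% of the variance and parted all 3 ammonium from all 3 nitrate libraries. Across tested features, Pearson's r of log2 CPM was 0.986 to 0.992 between ammonium libraries, 0.987 to 0.990 between nitrate libraries and 0.928 to 0.949 between the treatments. Features are not independent replicates, so these values describe the libraries only. Ammonium replicate 3 lay nearer to the nitrate libraries, at 49.1 on the first component against 72.8 and 68.1 for replicates 1 and 2. The nitrate libraries lay between -64.7 and -60.7, with nitrate replicate 3 at -60.7, nearest to the ammonium libraries. The second component (7.2% of the variance) set the libraries numbered 3 of both treatments, at -29.7 and -24.3, apart from the other four.

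**Figure D1:**
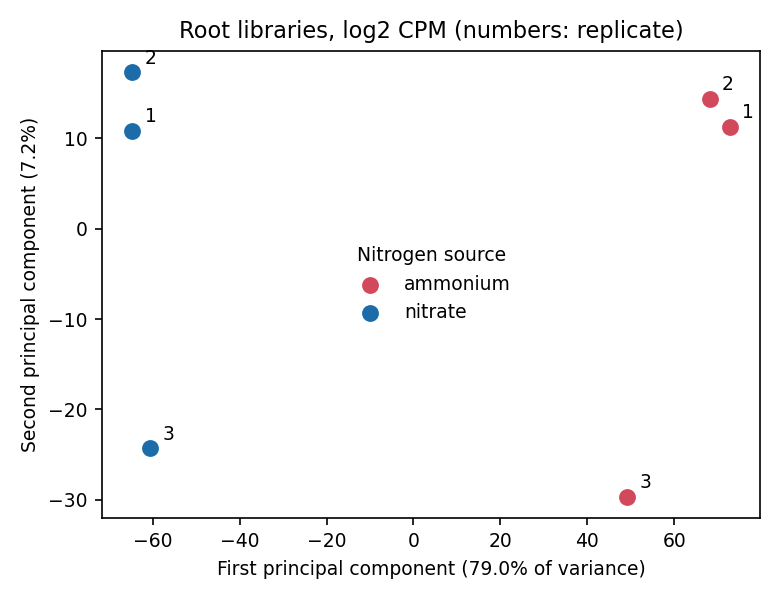
Position of the 6 root libraries on the first and second principal components of log2 CPM (no unit), coloured by nitrogen source and numbered by replicate. The nitrogen sources separate on the first component, where ammonium replicate 3 (49.1) lies nearest to the nitrate libraries (-64.7 to -60.7).

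Ammonium nutrition was associated with a different level of 9800 of the 23694 tested root features. Of these, 4544 were higher and 5256 were lower under ammonium than under nitrate, and 13894 did not pass the threshold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Most changes were small: the median log2 fold change of the higher features was 0.62 (interquartile range 0.41 to 1.09) and that of the lower features -0.77 (interquartile range -1.18 to -0.48). A difference of more than 2-fold was found for 1281 higher and 1789 lower features. The libraries of the treatments did not overlap for 9644 of the 9800 called features. Over all tested features the share without overlap was 54.4%, where chance gives 10%. The median SE of a log2 fold change was 0.13. No library came from roots without nitrogen or with both sources. Induction by ammonium thus cannot be told from repression by nitrate, nor the reverse. Rises and falls are given from nitrate to ammonium.

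The direction of change varied with its size. Lower features were in the majority among all calls, of which 46.4% were higher, and among changes above 2-fold, of which 41.7% were higher. Above 8-fold, 219 features were higher and 124 lower. Above 32-fold, 61 were higher and 18 lower. Features changed by more than 8-fold were more often higher than features changed by at most 2-fold, of which 3263 were higher and 3467 lower (Fisher's exact test, two-sided p = 2.6e-08, odds ratio 1.88, 1 test; features are not independent replicates). The majority of higher features above 8-fold was also found for features with a mean of at least 5 CPM in the higher group, 140 higher and 62 lower. Of the features above 8-fold, 26 higher and 13 lower ones had at most 3 counts in total in the group where they were lower, so that their fold depends on the prior count. With no abundance filter, the number above 8-fold was 283 higher and 210 lower, which moved the lower count by more than 1.5 times.

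**Figure D2:**
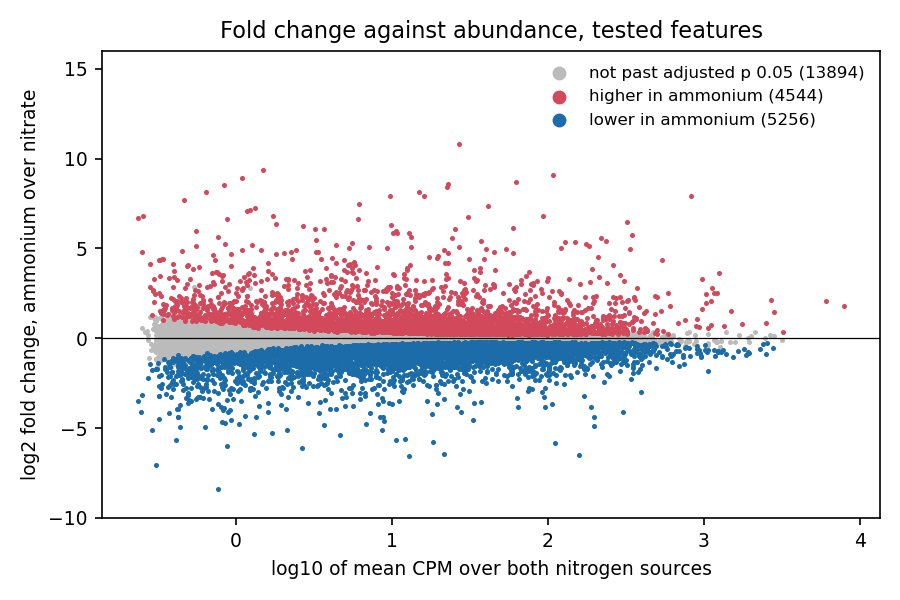
Log2 fold change (ammonium over nitrate) of each of the 23694 tested features against log10 of its mean CPM over both nitrogen sources, coloured by call at an adjusted p of 0.05. The upward changes reach further from 0 than the downward ones, while the lower features (5256) outnumber the higher ones (4544).

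The largest rises, among features that met the abundance minimum, were those of BRADI_2g28470v3 and BRADI_2g45143v3, both with the chromosome digit 2. BRADI_2g28470v3 was nearly absent from nitrate roots, with 2 counts over the 3 nitrate libraries (0.026 ± 0.044 CPM, SD, n = 3). It reached 54.2 ± 16.6 CPM (SD, n = 3) in ammonium roots, where the libraries held 993 to 1898 counts. Its log2 fold change was 10.80 (SE 0.50, edgeR adjusted p = 4.6e-06). The ratio of its counts was 2101 with an exact 95% interval of 581 to 17356, so its size is poorly bounded. Without nitrate replicate 2, which held both nitrate counts, the log2 fold change of BRADI_2g28470v3 was 13.53. No nitrate count was then left, so this value is set by the prior count. Without nitrate replicate 1 the log2 fold change was 10.21. BRADI_2g45143v3 rose from 0.377 ± 0.304 CPM to 215 ± 63.1 CPM (SD, n = 3 each), a 549-fold difference (log2 9.10, SE 0.41, edgeR adjusted p = 4.3e-06). Without nitrate replicate 2 its log2 fold change was 9.83. In ammonium replicate 3, BRADI_2g28470v3 and BRADI_2g45143v3 stood at 35.9 and 142 CPM, below the other ammonium libraries (58.7 and 68.1 CPM, and 251 and 252 CPM).

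By the same rule, the largest falls were those of BRADI_3g01277v3 and BRADI_3g01270v3. BRADI_3g01270v3 fell from 314 ± 43.1 CPM under nitrate to 3.48 ± 0.702 CPM under ammonium (SD, n = 3 each), an 89.9-fold difference (log2 -6.49, SE 0.18, edgeR adjusted p = 3.7e-07). BRADI_3g01277v3 fell from 25.6 ± 5.29 CPM to 0.267 ± 0.169 CPM (SD, n = 3 each), a 93.5-fold difference (log2 -6.55, SE 0.32, edgeR adjusted p = 5.4e-06). In ammonium replicate 3, BRADI_3g01277v3 stood at 0.072 CPM, below the other ammonium libraries (0.371 and 0.359 CPM), and BRADI_3g01270v3 at 3.32 CPM, between them (4.25 and 2.87 CPM). The ammonium libraries held 2 to 11 counts of BRADI_3g01277v3 and 80 to 126 counts of BRADI_3g01270v3. The pair are direct neighbours (1 place apart) in the order of locus numbers. They belong to a run of 5 consecutive tested features that were all lower under ammonium by more than 2-fold, with absolute log2 fold changes of 1.74 to 6.55. Since the counting options are not known, reads shared between similar neighbouring genes cannot be ruled out for the 2 features.

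**Figure D3:**
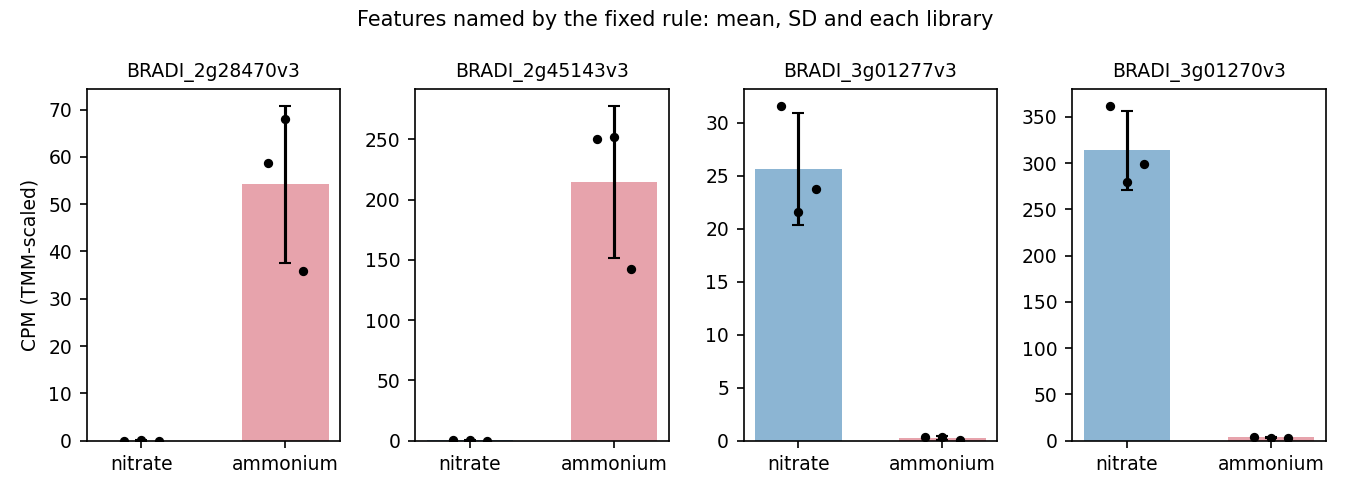
CPM (TMM-scaled) of the 4 named features under nitrate and ammonium; bars are means, error bars SD and points the 3 libraries of each group. BRADI_2g28470v3 and BRADI_2g45143v3 are near 0 under nitrate, and BRADI_3g01277v3 and BRADI_3g01270v3 fall to 0.267 and 3.48 CPM under ammonium.

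A few very abundant transcripts took a larger part of the root transcriptome under ammonium. The most abundant feature of each library held 1.24% ± 0.113 of all counts in ammonium roots and 0.366% ± 0.0219 in nitrate roots (SD, n = 3 each). The 10 most abundant features of each library held 4.96% ± 0.109 and 3.00% ± 0.102, respectively. The 100 most abundant held 15.96% ± 0.282 and 14.1% ± 0.285. All 3 differences gave p = 0.1 in a two-sided exact permutation test, the smallest value this design allows, with the ammonium value higher in every library. Of the 10 features most abundant over all libraries, 5 were higher and 2 lower under ammonium. The first of them rose 3.40-fold (log2 1.76, SE 0.13, edgeR adjusted p = 2.4e-05) and the second 4.26-fold (log2 2.09, SE 0.17, edgeR adjusted p = 4.5e-05). Among the 100 most abundant features, 25 were higher and 39 lower.

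Changes were found at every level of abundance, and the share called increased with abundance. It was 25.6% of 2277 features under 1 CPM, 36.4% of 7998 features from 1 to 10 CPM, 45.7% of 11230 features from 10 to 100 CPM and 53.6% of 2189 features at 100 CPM or more. The median SE fell along the same classes, from 0.38 to 0.19, 0.10 and 0.09. Among called features the share that was higher under ammonium was 42.2%, 47.2%, 48.0% and 39.0% in these classes.

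The changed features were spread over all 5 chromosomes, read from the digit in the locus identifier. The share called was 41.4% of 6879 features on chromosome 1, 42.4% of 5362 on chromosome 2, 41.5% of 5325 on chromosome 3, 40.02% of 3853 on chromosome 4 and 41.8% of 2202 on chromosome 5. Neither the share called (chi-square test over features, p = 0.27) nor the direction of all calls (p = 0.20) differed detectably between chromosomes. Both adjusted p-values over the 2 tests were 0.27. Above 2-fold, 320 features were higher and 509 lower on chromosome 1, and 345 and 394 on chromosome 2. The counts were 274 and 423 on chromosome 3, 215 and 269 on chromosome 4 and 122 and 194 on chromosome 5. Whether direction differs between chromosomes at this level was not tested.

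Features with the identifier prefix ENSRNA were called less often than locus features of the same abundance. Of 69 tested, 8 were higher under ammonium, 0 were lower and 61 did not pass the threshold of the edgeR test. Among 10000 random lists of locus features matched on mean abundance, the median number of calls was 21, with a central 95% range of 14 to 28, and 0 lists had as few as 8. The median log2 fold change of the ENSRNA features was 0.21, against -0.03 in the matched lists (central 95% range -0.23 to 0.17). It lay above that range, so fewer calls do not mean that the set was unchanged. Their median SE was 0.30, and the lists were not matched on SE. As a whole, these features held 0.376% ± 0.0215 of all counts under ammonium and 0.392% ± 0.0397 under nitrate (SD, n = 3 each; exact permutation test, two-sided p = 0.7). A single feature took 81.6% to 84.8% of the ENSRNA counts of each library.

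Features detected under only one nitrogen source were rare. With 0 counts in all 3 nitrate libraries and a mean of at least 20 counts in ammonium roots, 6 features were found, the most abundant with a mean of 85.7 counts. The reverse, 0 counts in all 3 ammonium libraries, held for 1 feature with a mean of 40.3 counts in nitrate roots.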

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

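Thinning and robust dispersions were chosen after the data had been seen; the other alternatives were fixed before the data were examined. The number of changed features (9800) stayed within 1.5 times under 15 of 16 alternatives. The exception is by construction the added minimum of 2-fold, which left 3070 features, 1281 higher and 1789 lower. Other scalings, filters and tools called 9273 (DESeq2 Wald test) to 9861 (library size only). Leaving out 1 library gave 7103 (without ammonium replicate 1) to 9898 (without ammonium replicate 3). The higher features then numbered 3110 to 4469 and the lower ones 3993 to 5429. With the replicate number as a block, 10526 features were called, 4892 higher and 5634 lower, of which 9556 were among the 9800 with the same direction. The block changed no call of a named feature. Thinning to the shallowest library gave 9462 and robust dispersions 9822. No feature of the 9800 was called in the opposite direction in any of the 15 refits. The share of higher features was 42.8% to 48.2% of all calls and 57.4% to 67.8% of changes above 8-fold over these refits. The median feature moved by at most 0.016 on the log2 scale. The 4 named features kept their direction and an adjusted p under 0.05 in all 15 refits, the highest being 0.00021. Rare features were measured less precisely, with a median SE of a log2 fold change of 0.38 under 1 CPM and 0.09 at 100 CPM or more; how much of this is depth was not tested. The alternatives planned for gene lists were not run, since no identifier could be matched to a product name.

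Only 1 of the 10 splits of the 6 libraries into 3 and 3, the real one, gave as many calls: 9800, against 0 in the highest of the other splits. With 10 splits the share cannot fall under 0.05. Each other split also puts libraries of both treatments in both groups, so the treatment difference adds to the spread within groups. Few calls were thus to be had in those splits in any case, and their 0 calls decide nothing about chance. The other 3 splits that part all the replicate numbers, as the real one does, and the 6 that part 1 number gave 0 calls.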

Other observations

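The tests of the log-scale displacement, of the factor shared by the libraries numbered 3 and of the shuffled locus order were chosen after the result they bear on had been seen. Bootstrap intervals were drawn over features or pairs of features, which are not independent replicates, and hold no spread between pools.

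Ammonium replicate 3 lay nearer to the nitrate libraries than the other ammonium pools did. The distance of this library to the nitrate mean on the first principal component was 0.841 of the mean distance of the others. The features used here were called and changed more than 4-fold in a fit without this library. Their mean was at least 20 CPM in the higher group. Among the 213 higher in ammonium, this library lay a median of 0.434 of the way back to the nitrate level on the linear CPM scale. Among the 137 higher in nitrate it lay 0.0708 of the way. An admixture of nitrate RNA or reads in a fixed share would displace both sets alike. The medians differed by -0.363 (95% bootstrap interval -0.392 to -0.310), which argues against it as the whole cause. The same difference was 0.224 for ammonium replicate 1 and 0.143 for replicate 2, each set against means that include replicate 3. A displaced replicate 3 moves those means and so pushes replicates 1 and 2 the opposite way. Their differences, opposite in sign to that of replicate 3, cannot show whether unequal medians are particular to it. Depth is argued against by the totals: ammonium replicates 2 and 3 held 27746315 and 27525771 counts but lay at 68.1 and 49.1 on the first component. Thinning all libraries to equal depth, which could hardly move the ratio given these totals, left it at 0.842 at most over 5 thinnings and decides nothing. For these 350 strongly changed features, a factor acting alike on both libraries numbered 3 is argued against by the correlation of their deviations, -0.117 (95% bootstrap interval -0.238 to 0.00207). Over all tested features that correlation was 0.113, and both libraries lay apart on the second principal component (-29.7 and -24.3), so such a factor stays open for the other features. Nitrate replicate 3 was also the nitrate library nearest to ammonium on the first component, at -60.7 against -64.6 and -64.7. A factor that moved the libraries numbered 3 towards each other would not give a positive correlation, so this test cannot exclude it. On the log scale the median displacement was 0.192 (interquartile range 0.058 to 0.275) for the features higher in nitrate and 0.193 (0.088 to 0.308) for those higher in ammonium, a difference of -0.0017 (95% bootstrap interval -0.047 to 0.038). For ammonium replicates 1 and 2 this difference was 0.036 and 0.041, again against means that include replicate 3. These values cannot show whether similar medians in both directions are particular to replicate 3. Single features varied widely around the medians of replicate 3. BRADI_3g01277v3, which was lower under ammonium, lay further from nitrate in this library (0.072 CPM) than in the other ammonium libraries (0.371 and 0.359 CPM). A candidate explanation is a response reduced by a similar median share in both directions in this pool, which is a hypothesis found and tested on the same data. Dilution by RNA that lacks these transcripts would lower both sets. Of the 137 features higher in nitrate, 78.8% instead lay towards nitrate in this library (interquartile range of the linear displacement 0.019 to 0.125). This argues against such dilution as the whole cause. Dilution by RNA that holds these transcripts and differences in growth or harvest stay open.

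Neighbouring genes tended to change together. In the order of locus numbers, the log2 fold changes of adjacent tested features correlated at 0.164 across 23621 features, and at 0.053 and 0.034 for features 2 and 3 places apart. Chance order is argued against, since 0 of 1000 orders shuffled within chromosomes reached the adjacent value, and the highest gave 0.021. Among features changed by more than 2-fold, 204 adjacent pairs were both higher and 282 both lower, 2.94 and 2.08 times the mean of the shuffled orders, while 140 pairs went in opposite directions, against a shuffled mean of 193. There were 20 runs of at least 4 consecutive features changed more than 2-fold in the same direction, against at most 6 in a shuffled order. Reads of a gene model counted in its neighbour stay open: pairs within 4 times of each other in abundance and pairs at least 16 times apart correlated at 0.175 and 0.161, a difference of 0.014 (95% bootstrap interval -0.068 to 0.094). Tandem gene copies that respond alike could give the same pattern, and this was not tested, because no sequences were at hand.

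The run of locus-number neighbours that holds BRADI_3g01270v3 and BRADI_3g01277v3 had 4 strongly lower features in a row. Besides this pair, the features directly before and after it had log2 fold changes of -5.85 and -5.79 (edgeR adjusted p = 2.1e-06 and 4.4e-06). Together the 4 fell from 219, 314, 25.6 and 36.5 CPM under nitrate to 3.79, 3.48, 0.267 and 0.656 CPM under ammonium. The next feature after them was at 0.31 (adjusted p = 0.054) and the one after that at -0.01 (adjusted p = 0.93). Before them, the nearest feature, which has under 1 CPM, was at -1.74 (adjusted p = 0.0092) and the next at -0.51 (adjusted p = 0.00074), both also called lower. The change of -0.51 is smaller in size than the median of all lower features (-0.77). Whether the change fades with distance from the 4 was not tested. The run was described after its values had been seen.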
